A study of Bos taurus with 24 samples.

How the data were processed

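Bulk RNA sequencing of adrenal gland tissue from 24 female calves was analysed from tables of gene counts, 1 table per calf. The calves fell into 4 groups of 6, defined by exposure before birth (in utero heat stress, IUHS, or in utero cooling, IUCL) and by age at tissue collection (birth, day 0, or weaning, day 63). Groups were taken from the labels, and each library was named by the number in its title. Total RNA was extracted from the tissue with TRIzol and sequenced at a commercial centre, per the labels' protocols.

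The values deposited by the authors were raw, unnormalised read counts per gene for 27570 Ensembl bovine gene IDs. Per the submitters' processing notes, the tools used were FastQC 0.11.7, Trim Galore 0.4.4, HISAT2 and HTSeq, with the genome build ARS-UCD1.2. The versions of HISAT2 and HTSeq, the annotation release and the strand setting of the counting were not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical gene copies, could therefore have been split or pooled between IDs, and single-ID values carry that uncertainty.

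The count tables pair no ID with a gene name. The table of 37063 bovine genes at hand held an Ensembl ID for 0 of its genes, so no ID could be matched to a name with it. This says nothing about whether the IDs have names. The 37 gene lists fixed before the data were examined (steroidogenesis, chromaffin cells, immune cells, heat shock proteins and others), the cell type markers and the tests of these lists were for that reason not run. Values of named adrenal genes are not reported here. The rule for named genes, written for gene symbols, was applied to IDs in a shortened form. For the change with age, it took the ID with the largest mean change and the ID with the smallest p in each direction, among IDs past the threshold in both treatments, with a mean CPM (counts scaled by library size) of at least 1 and no library holding over 50% of the summed CPM. For heat stress against cooling at birth and at weaning, where none passed in edgeR, the rule took the ID with the smallest edgeR p in each direction. The mean CPM minimum was the same, and the 50% limit was applied over the compared libraries. Such IDs were not taken for the average and the interaction. An ID called by DESeq2 and not by edgeR was also named where there was 1 such ID, which was a choice made after its values were seen. ENSBTAG00000012333 at weaning was taken in both ways.

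Genes were tested with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr (minimum count 10, minimum total count 15), which left 15693 genes, and 4742 IDs had a count of 0 in every library. Libraries were scaled by TMM. All 24 libraries entered 1 quasi-likelihood model (robust dispersion and robust prior) with a mean per group, so that the 4 groups shared 1 estimate of the spread. The common biological coefficient of variation was 0.295. Heat stress was compared with cooling at birth, at weaning and averaged over both ages, and the difference between the treatment effects at the 2 ages was tested as an interaction. Weaning was compared with birth within each treatment. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are given as log2 values with standard errors (SE) from the model, and CPM values are TMM-scaled, given as mean ± SD over the 6 calves of a group.

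Principal components were computed on log2 CPM (prior count 2) of the 2000 most variable genes. The distance between whole profiles was measured as the squared distance between group means per gene, corrected for the spread within groups, and was tested by an exact permutation test over the 462 splits of 12 libraries into 2 groups of 6. The difference between the age distances of the 2 treatments was tested with 100000 permutations. These distance tests were chosen after the first counts of genes had been seen. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the distances and matplotlib 3.10.9 for plots.

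The model was tested on simulated counts drawn from each gene's mean over all 24 libraries, the library sizes and the fitted dispersions. In each run 200 of 15693 genes were changed, with 5 runs per comparison. Genes were drawn independently, with no other difference between groups and no axis shared between genes, which is simpler than the real data. At 2-fold, 58.8% of 250 planted changes were recovered for heat stress against cooling at birth, 61.6% at weaning, 75.2% averaged over ages and 41.6% for the interaction. For the change with age, 62.0% were recovered in cooled and 59.2% in heat-stressed calves. Between 3.10% and 5.97% of the calls in each comparison were unplanted genes.

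Libraries were compared in pairs before they were averaged. The smallest chi-square per degree of freedom over 276 pairs was 16.3, so no pair differed by as little as sampling noise, and every library counted as a separate replicate. Pearson's r of log2 CPM across genes, which are not independent replicates, lay between 0.916 and 0.978 for libraries of the same group.

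The alternatives planned before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample quality weights, DESeq2 size factors in edgeR, other low-count filters, a fit without robust dispersion, a fit on only the 12 libraries compared, other thresholds, 1 surrogate variable (sva 3.50.0), the title number as a block at birth, and a fit without each library in turn. Thinning of all libraries to the smallest total, a fit without libraries set apart on a principal component and the newer edgeR quasi-likelihood fit were added after seeing the data.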

Results

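Adrenal glands of 24 female calves were profiled by RNA sequencing to examine how heat exposure before birth shapes the gland, which makes glucocorticoids, mineralocorticoids and adrenal androgens in its cortex and catecholamines in its medulla. Tissue came from 6 calves per group: in utero cooled (IUCL) and in utero heat-stressed (IUHS) calves at birth (day 0), and calves of both treatments at weaning (day 63). Total counts per library ranged from 12261651 to 19012206. The group means were 15762067 ± 1914578 in IUCL and 15201327 ± 1735221 in IUHS calves at birth, and 14429943 ± 1460007 in IUCL and 14043782 ± 1357464 in IUHS calves at weaning (SD, n = 6 each). Between 18170 and 18450 genes had at least 1 count on average in each group, and 15693 genes were tested. The files do not pair gene IDs with names, so genes are given by Ensembl ID.

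Age was the main axis of variation between the adrenal glands. The first principal component held 25.7% of the variance of the 2000 most variable genes and separated all 12 birth libraries, with scores from -35.3 to -13.2, from all 12 weaning libraries, with scores from 16.99 to 35.0. The second component held 12.6% and separated neither ages nor treatments. Within each age, the IUHS and IUCL calves overlapped on both components.

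**Figure D1:**
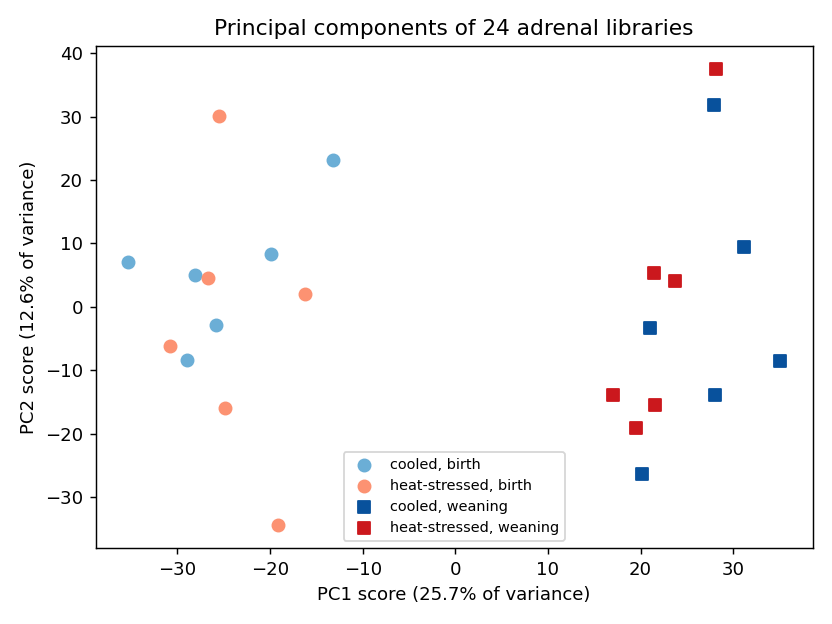
Scores of the 24 libraries on the first (x axis, 25.7% of variance) and second (y axis, 12.6%) principal components of log2 CPM of 2000 genes, 1 point per calf, coloured by treatment and age. Birth libraries lie at -13.2 or below and weaning libraries at 16.99 or above on the first component, and treatments overlap within each age.

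The change of the adrenal transcriptome between birth and weaning was examined in cooled calves first. In these calves 1876 of 15693 genes changed, 876 of them higher and 1000 lower at weaning. A change of at least 2-fold was seen for 371 higher and 407 lower genes, and of at least 4-fold for 127 higher and 126 lower genes. The median size of the change was 0.84 on the log2 scale in both directions. The tests were edgeR's quasi-likelihood tests, and the whole-profile distance between the ages was 0.244 per gene, larger than in any other of the 462 splits of these 12 libraries (exact permutation p = 0.00216, the smallest possible; 0.00433 after adjustment over 4 distances).

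In heat-stressed calves 991 genes changed between birth and weaning, 416 higher and 575 lower. At least 2-fold changes numbered 154 higher and 323 lower, and at least 4-fold changes 41 higher and 79 lower. The median size of the change was 0.74 for genes that rose and 1.12 for genes that fell. The profile distance between ages was 0.168 per gene, again larger than in any other of the 462 splits (exact permutation p = 0.00216, adjusted 0.00433). The count moved by more than 1.5 times without IUHS calf 8 at birth, to 624, and without IUHS calf 29 at weaning, to 653. It rose to 1559 with 1 surrogate variable and to 1800 with sample quality weights.

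The genes that changed with age overlapped between treatments. Of the genes that passed, 253 were higher and 358 were lower at weaning in both treatments, against 23.2 and 36.6 for independent lists of these sizes, and 0 passed in opposite directions. These treatments share no libraries, but the model shared 1 estimate of the spread per gene. The 2 lists were therefore not fully independent, which the expected numbers do not allow for. Of the 876 genes higher at weaning in cooled calves, 94.9% had the same sign in heat-stressed calves, and of the 1000 lower genes 96.0% did. The 253 shared higher genes took 2.01% ± 0.215 of all counts at birth and 3.45% ± 0.284 at weaning in cooled calves, and 1.97% ± 0.148 and 3.30% ± 0.145 in heat-stressed calves (SD, n = 6 each). The 358 shared lower genes fell from 2.91% ± 0.144 to 1.60% ± 0.0545 in cooled calves and from 2.88% ± 0.268 to 1.63% ± 0.107 in heat-stressed calves. These shares describe genes chosen by the same test. Across all 15693 genes, the log2 changes with age in cooled and heat-stressed calves had a Pearson's r of 0.690, with genes not being independent replicates. Calls were found at all levels of abundance: of the genes called in both treatments, 67 higher and 138 lower were among the 5231 least abundant genes tested, 79 and 129 among the 5231 of middle abundance, and 107 and 91 among the 5231 most abundant.

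**Figure D2:**
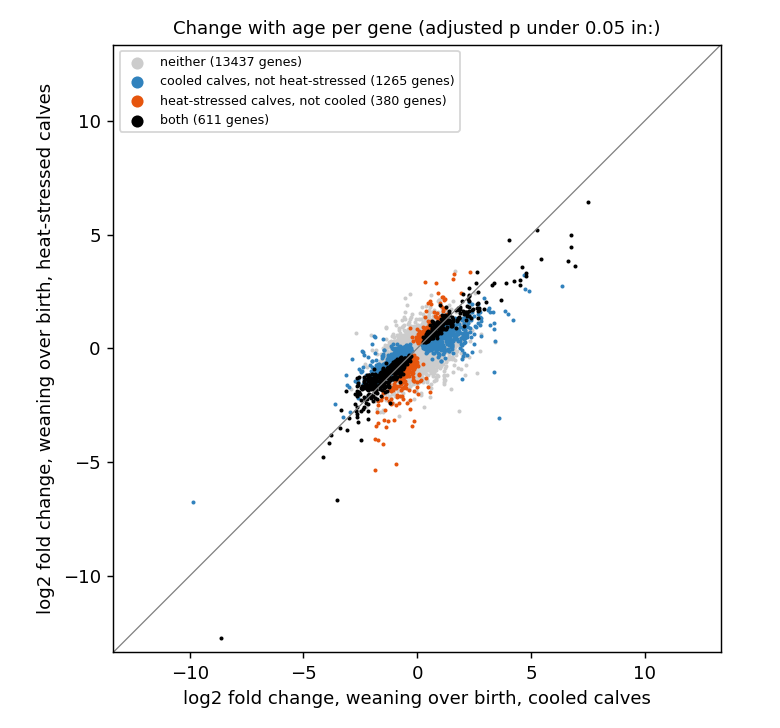
Log2 fold change from birth to weaning in cooled calves (x axis) against heat-stressed calves (y axis), 1 point per tested gene, coloured by the treatments in which the adjusted p was under 0.05. The grey line marks equal changes; the 611 genes called in both treatments lie in the same-sign quadrants.

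Among abundant IDs, ENSBTAG00000012330 rose at weaning by 2.20 ± 0.19 (log2, SE) in cooled calves (edgeR adjusted p = 2.97e-07) and by 1.55 ± 0.19 in heat-stressed calves (edgeR adjusted p = 7.24e-05). Its level went from 70.2 ± 13.2 to 323 ± 111 CPM in cooled calves and from 72.8 ± 17.97 to 213 ± 35.8 CPM in heat-stressed calves, and the lowest weaning library, at 161 CPM, lay above the highest birth library, at 105 CPM. The treatments' changes for this ID did not differ past the threshold (interaction log2 -0.65 ± 0.26, edgeR adjusted p = 0.893). ENSBTAG00000013411 fell by 1.23 ± 0.14 in cooled calves (edgeR adjusted p = 1.02e-05) and by 1.21 ± 0.14 in heat-stressed calves (edgeR adjusted p = 7.11e-05), from 1178 ± 116 to 503 ± 38.0 CPM and from 1206 ± 336 to 523 ± 69.0 CPM. Here the highest weaning library, at 640 CPM, lay below the lowest birth library, at 710 CPM.

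The IDs named for the largest mean change, 1 in each direction, were near the detection floor at 1 age. ENSBTAG00000048135 had 0 to 4 counts in cooled and 0 to 11 counts in heat-stressed calves at birth, and 19 to 434 and 30 to 253 counts at weaning. Its mean level at weaning was 10.98 ± 8.58 CPM in cooled and 10.7 ± 7.17 CPM in heat-stressed calves (edgeR adjusted p = 3.76e-05 and 0.000231). ENSBTAG00000008319 went the other way, from 1.95 ± 1.45 to 0.0981 ± 0.114 CPM in cooled calves and from 2.85 ± 2.38 to 0.0948 ± 0.1001 CPM in heat-stressed calves (edgeR adjusted p = 0.00215 and 0.00186), with at most 5 counts in any weaning library. The size of these changes depends on the few counts at the lower age.

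**Figure D3:**
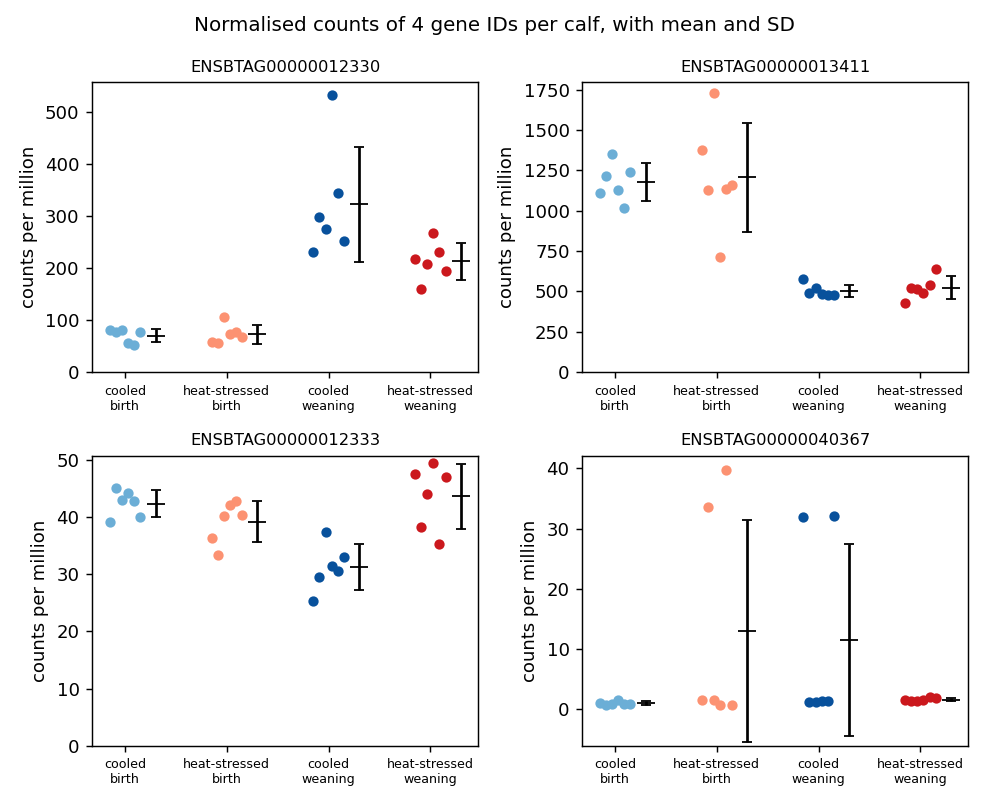
Normalised counts (y axis, CPM) of 4 IDs in each of the 4 groups (x axis), 1 point per calf, with the group mean and SD as a bar beside the points. ENSBTAG00000012330 lay higher and ENSBTAG00000013411 lower in all 12 weaning libraries than in all 12 birth libraries; ENSBTAG00000012333 and ENSBTAG00000040367 are the IDs that DESeq2 called and edgeR did not.

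Heat stress was compared with cooling at birth to ask whether the gland differed at the end of the exposure. At birth 0 of 15693 genes passed the threshold in edgeR, in DESeq2 and in limma-voom. The edgeR test gave 617 genes at an unadjusted p under 0.05, where 785 are expected by chance, DESeq2 gave 723 and limma-voom gave 632. The median absolute log2 difference was 0.12, with a median SE of 0.20. For 76.5% of the genes the 95% interval of the treatment effect lay within a 2-fold change in either direction. The ID named for the smallest p among those higher in heat-stressed calves was ENSBTAG00000037949 (log2 3.59 ± 0.86, edgeR unadjusted p = 0.000355). It measured 173 ± 243 against 14.3 ± 5.46 CPM, with IUHS calves 1, 2 and 4 at 531, 437 and 51.3 CPM. IUHS calves 5, 7 and 8, at 3.49, 6.14 and 10.1 CPM, lay below the lowest cooled calf, at 10.8 CPM. Over the alternative fits its log2 difference ranged from 0.94 to 3.85. Among those lower it was ENSBTAG00000000764 (log2 -0.43 ± 0.12, edgeR unadjusted p = 0.00148), at 34.5 ± 5.31 against 46.6 ± 8.74 CPM. The profile distance between treatments was -0.00621 per gene (exact permutation p = 0.608), which did not exceed the spread between calves.

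At weaning, 63 days after birth, 0 genes passed in edgeR and limma-voom, and 1 passed in DESeq2. Genes at an unadjusted p under 0.05 numbered 1097 in edgeR, 1190 in DESeq2 and 1030 in limma-voom, against 785 expected by chance. Without each weaning library in turn, edgeR gave from 645 such genes (without IUCL calf 19) to 1335 (without IUHS calf 23). The ID that DESeq2 called, ENSBTAG00000012333, measured 43.5 ± 5.64 CPM in heat-stressed and 31.2 ± 4.02 CPM in cooled calves (SD, n = 6 each), with overlapping ranges of 35.2 to 49.4 and 25.3 to 37.4 CPM. Its log2 difference was 0.48 ± 0.10 in edgeR (adjusted p = 0.61; DESeq2 adjusted p = 0.0481). At birth the same ID measured 39.1 ± 3.60 CPM in heat-stressed and 42.3 ± 2.33 CPM in cooled calves. ENSBTAG00000011743 was the ID named for the smallest p among those lower in heat-stressed calves at weaning. It measured 7.12 ± 1.38 CPM in heat-stressed and 14.3 ± 4.90 CPM in cooled calves at weaning, with ranges of 5.01 to 8.57 and 8.70 to 21.9 CPM. Its log2 difference was -1.01 ± 0.23 in edgeR (adjusted p = 0.61). The 95% interval lay within 2-fold for 77.1% of the genes, and the profile distance was 0.00477 per gene (exact permutation p = 0.344).

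**Figure D4:**
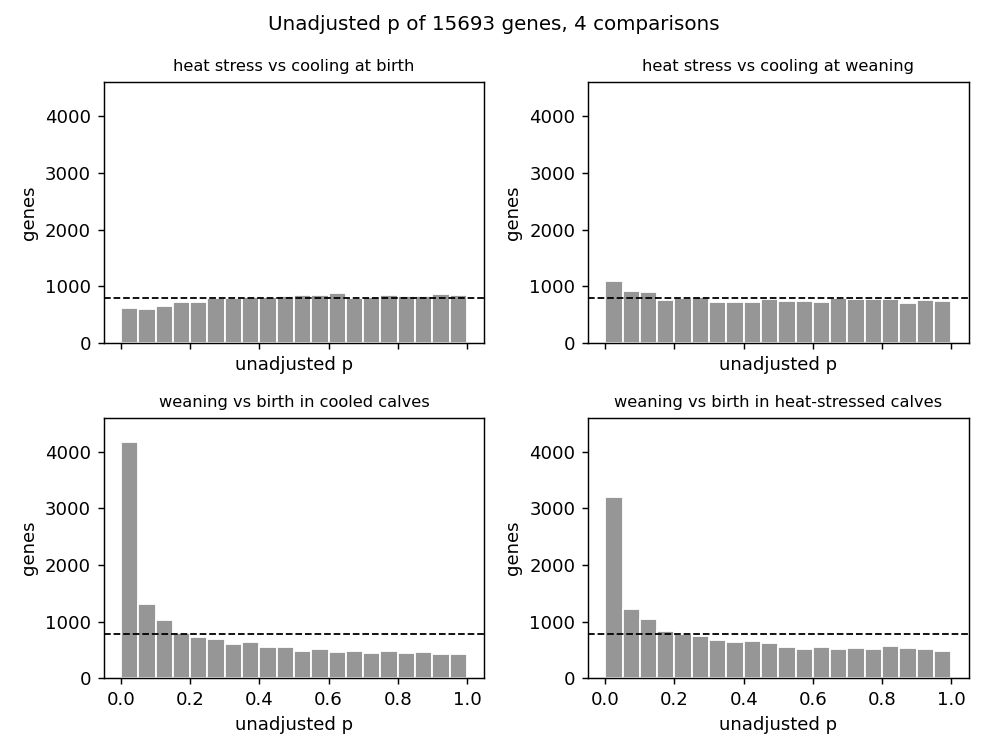
Number of genes (y axis) per bin of unadjusted edgeR p (x axis) in 4 comparisons; the dashed line marks the 785 genes per bin expected by chance. The lowest bin holds 617 genes for treatment at birth, 1097 for treatment at weaning, 4167 for age in cooled and 3206 for age in heat-stressed calves.

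Averaged over both ages, heat stress and cooling differed in 0 genes past the threshold in edgeR, DESeq2 and limma-voom, with 724, 842 and 653 genes at an unadjusted p under 0.05. The averaged effect had the smallest median SE of the treatment comparisons, 0.14 on the log2 scale, and its 95% interval lay within 2-fold for 88.9% of genes. Treatment effects at birth and at weaning had a Pearson's r of -0.0423 across genes (permutation p = 0.744, 1000 shuffles of the calves), within the range of -0.279 to 0.264 that holds 95% of the shuffles.

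The test of whether the treatment effect differed between birth and weaning, which equally tests whether the change with age differed between treatments, called 0 genes in edgeR and limma-voom and 1 in DESeq2. Genes at an unadjusted p under 0.05 numbered 872, 800 and 966. The larger number of genes past the threshold with age in cooled than in heat-stressed calves (1876 against 991) was thus not accompanied by any gene whose change was shown by edgeR to differ. The profile distances between ages, 0.244 and 0.168, did not differ past the threshold (permutation p = 0.120, 100000 permutations). The ID that DESeq2 called, ENSBTAG00000040367 (adjusted p = 0.0116; edgeR adjusted p = 0.893), had 0.925 ± 0.329 CPM in cooled and 12.9 ± 18.5 CPM in heat-stressed calves at birth, and 11.5 ± 15.9 and 1.54 ± 0.255 CPM at weaning (SD, n = 6 each). The high means came from 2 heat-stressed calves at birth (39.8 and 33.5 CPM) and 2 cooled calves at weaning (32.1 and 31.9 CPM), while the group medians were 1.41 and 1.27 CPM. The 95% interval of the interaction lay within 2-fold for 61.2% of the genes, fewer than for any other treatment comparison.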

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

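The tests of profile distance, of thinned libraries and of libraries left out together were chosen after the first counts of genes had been seen. In 60 groups of 6 values, 6 values stood apart from the rest of their group by Dixon's test, where about 3 are expected by chance, since chance sets apart about 1 in 20 groups.

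IUHS calf 28 at weaning scored -35.9 on the third principal component, where the other 5 calves of its group scored from -2.11 to 6.79, and -14.6 on the fourth, where the others scored from -2.67 to 2.83. IUCL calf 3 at birth scored 41.8 on the fourth component, with the others from -5.00 to -1.83. Without both libraries, edgeR called 2171 genes with age in cooled calves and 795 in heat-stressed calves, and 0 in each of the treatment comparisons. IUCL calf 6 at birth had 3.18% of its counts in the genes lower at weaning in both treatments, above the range of 2.77% to 2.90% in the others. ENSBTAG00000048135 stood out in 2 birth libraries, at 0.213 CPM in IUCL calf 5 (others 0 to 0.0689) and at 0.659 CPM in IUHS calf 4 (others 0). The lowest weaning libraries were at 1.42 CPM in IUCL and 2.11 CPM in IUHS calves.

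The absence of genes past the threshold between treatments was weighed against technical explanations. As many calls were found in 100 of 100 splits drawn, the real split included, for each of the comparisons at birth, at weaning, averaged and for the interaction, as a real count of 0 must; the highest other counts were 13, 1, 65 and 1495. The last came from 1 of the 6 splits with any call, and what sets it apart was not tested. The leading unmodelled axis between libraries, entered as 1 surrogate variable, uncovered no gene past the threshold, with 0 calls at birth and weaning together, though it raised the age calls. Genes at an unadjusted p under 0.05 in edgeR numbered 633 at birth and 1466 at weaning with it, against 617 and 1097 without. Other splits were not run with this variable, so the rise at weaning was not weighed against chance. Further axes were not tested. Too few calves remains open as an explanation: 28% of planted 1.5-fold, 58.8% of 2-fold, 86.8% of 3-fold and 90.8% of 4-fold changes were recovered at birth, but simulated settings exclude nothing about the size and number of real changes, although over 50% at 2-fold had been set as evidence against it. A difference spread thinly over many genes may also remain, since the smaller exact permutation p of the profile distance was 0.3442 and the distance at weaning lay above its median over splits.

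Counts of genes at an unadjusted p under 0.05 in edgeR did not stand out from those of other splits. Of 100 splits, the real one included, as many such genes were found in 72 at birth (real 617, highest other 3042) and 23 at weaning (1097 and 2814). They were found in 49 for the average (724 and 3002) and 33 for the interaction (872 and 4386). In the real groups at weaning, the count ranged from 645 without IUCL calf 19 to 1335 without IUHS calf 23, each weaning library being left out in turn. With limma-voom sample quality weights there were 1201 such genes for the average and 1466 at weaning, against 785 expected by chance, and 0 past the threshold in both; other splits were not run with these weights. Without a low-count filter, edgeR tested 22828 genes and gave 1146 at birth, 1509 at weaning, 1300 for the average and 1384 for the interaction. These counts cannot be set against 785, which is the number expected for 15693 genes, since more are expected by chance when more genes are tested.

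Fewer genes passed with age in heat-stressed than in cooled calves, 991 against 1876. Each count on its own stood out from chance: 1 of 100 splits, the real split, gave as many, with 589 and 123 as the highest other counts. These splits tested each change with age and not the difference between the 2 counts. The difference in counts was not permuted, so chance remains open for it. The tables argue against a single library, since the count in cooled calves stayed above that in heat-stressed calves by at least 412 without any 1 of the 24 libraries, and against library depth, since the ratio of the counts was 1.853 with all libraries thinned to the smallest total. A larger spread between heat-stressed calves may also account for it: distances within groups were 0.587 against 0.535 at birth and 0.552 against 0.507 at weaning (smaller exact permutation p 0.7229), which left it open, and the near-equal SEs of both age comparisons cannot decide it, since the model shared 1 estimate of the spread. With the spread estimated from only the 12 libraries compared, the counts were 1824 in cooled and 688 in heat-stressed calves (ratio 2.65, against 1.89). Without each of the 24 libraries in turn, the ratio ranged from 1.43 to 2.88. With limma-voom sample quality weights the counts were 2653 and 1800 (1828 and 813 without weights). A smaller change with age in heat-stressed calves, the biological explanation the design offers, may also account for it, but the difference in distance (0.168 minus 0.244, -0.0758) had a permutation p of 0.1203.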

How the results depend on the processing

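None of the IDs named by the rule changed direction, in the comparison it was named for, under any alternative that tested it. Counts of genes have no direction, and the signs of all called genes were not compared between alternatives. Treatment comparisons gave 0 genes under every alternative except DESeq2, which called 1 gene at weaning and 1 for the interaction; the cause was not tested. For age in cooled calves, the count was 2840 at an adjusted p under 0.10 and 778 with a 2-fold minimum, as these thresholds dictate, and 1346 to 2078 without each library in turn. For age in heat-stressed calves it was 1613 and 477 under the same thresholds, 1800 with sample quality weights and 1559 with 1 surrogate variable (cause not tested), and 624 (without IUHS calf 8 at birth; 653 without IUHS calf 29 at weaning) to 1285 without each library in turn. DESeq2 called 2404 and 1458 genes with age, holding 1873 of the 1876 and 989 of the 991 genes of edgeR. Of the named IDs, ENSBTAG00000012333 at weaning passed in DESeq2 (log2 0.47, adjusted p 0.0481), with adjusted p from 0.0481 to 1 over its alternatives. The 4 age IDs passed in every alternative that tested them. ENSBTAG00000037949 and ENSBTAG00000000764 at birth and ENSBTAG00000011743 at weaning passed in none, with lowest adjusted p of 0.0708, 0.367 and 0.101 over their alternatives. The title number as a replicate block at birth gave 0 genes, but with 3 residual degrees of freedom this says nothing about stability. Numbers 1, 2, 5 and 7 were shared at birth, and no number was shared at weaning. Title numbers were not a stated pairing, so these calves were not taken as pairs. The deviations of same-numbered calves correlated at -0.123, -0.105, 0.169 and 0.295, against a mean of -0.00739 over other pairings. For numbers 5 and 7 the best-matching heat-stressed calf had the same number, and for numbers 1 and 2 it did not. Gene list tests (camera, fry) and the chromaffin score covariate were not run, since the gene table at hand held no Ensembl IDs to match to symbols. Depth limits the IDs with few counts most, and their fold changes are uncertain.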

Other observations

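The search for genes with an on-and-off pattern was made after the values of ENSBTAG00000040367 had been seen; its thresholds were then set without further looks. Across the 24 libraries, 8 genes had 2 levels separated by at least 3 log2 units, with at least 4 libraries at each level. The mean high level ranged from 4.14 to 293 CPM, and 4 to 16 libraries were at it. In 1 of these genes the levels followed age: all 12 birth libraries were at the high level and all 12 weaning libraries at the low level, with a mean of 0.00624 CPM at weaning. The mean of 32.2 CPM at birth was set by IUHS calf 4, at 299.8 CPM; the other 11 birth libraries ranged from 2.03 to 15.8 CPM, with a mean of 7.93 CPM. In the other 7 genes both levels occurred at both ages. ENSBTAG00000040367, the ID that DESeq2 called for the interaction and which was chosen after its values were seen, was among them: 4 libraries averaged 34.3 CPM and the rest 1.19 CPM.

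Technical and treatment explanations for these 8 genes were tested. Counting and overdispersion noise alone gave at most 3 such genes in any of 20 simulated draws. Cells or RNA of another kind in some libraries might switch genes together. Of the 28 pairs of genes, 0% split the 24 libraries in nearly the same way (phi of at least 0.8). A pair of genes high in unlike numbers of libraries, such as 7 and 15, cannot reach this phi. The 0% therefore argues only against 1 source that switches all 8 genes alike. Sharing between some of the genes was not tested. The treatment group was associated with 0% of the genes by Fisher's exact test over both ages, with a lowest exact p of 0.193. Pooled over ages, this test could not show a treatment difference that reverses with age. ENSBTAG00000040367 was high in 0 cooled and 2 heat-stressed calves at birth, and in 2 cooled and 0 heat-stressed calves at weaning. For such a pattern the test decides nothing. For the 7 genes that did not follow age, inherited differences between calves, or reads shared with gene copies, may be candidate explanations; neither was tested, since the labels give no genotype or parentage and sequences were not used here.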
